A study of Mus musculus with 14 samples.

How the data were processed

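RNA-seq libraries were made from total RNA with an Illumina kit after TRIzol extraction and column cleanup, per the labels' protocols. The 14 libraries came from primary cortical neurons of E16.5 mouse embryos, cultured on poly-ornithine and fibronectin in neurobasal plus medium with B27 plus. Spontaneous firing was silenced on day 5 in vitro with 1 µM tetrodotoxin, which blocks sodium channels, and 100 µM APV, which blocks NMDA receptors. On day 6 cultures were depolarised with 50 mM KCl for 1 h or left as basal controls, per the labels' protocols. Groups were read from the sample labels: SA carried an alanine and SE a glutamate in place of serine 1382 of BRG1, and each mutant had wild-type littermate controls, called the wild type of its line. There were 8 groups of 2 libraries each, except the wild type of the SE line, which had 1 library per treatment.

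The authors quantified transcripts with kallisto 0.43.1 against GRCm38 (mm10), per the submitters' processing notes; kallisto assigns reads to transcripts by pseudoalignment and needs no genome alignment. The deposited estimated count of a transcript is the share of reads that kallisto's model gave it and need not be a whole number: 65.6% of nonzero gene values were not whole. The authors also deposited TPM values, which are divided by effective transcript length and sum to the same total in each library. Deposited matrices gave both units per transcript (131100 transcripts) and per gene symbol (52459 symbols). The gene values equalled the sums of their transcripts to within 5.09e-11 counts; how the authors summed them is not given in the sources used here. Of the transcript identifiers, 127421 matched GENCODE M21 with their version and 130634 without it. Coordinates below are 1-based GRCm38 positions from that annotation. Reads shared between near-identical paralogs were split by kallisto's model, so counts of such genes carry an error that was not measured here. Strand-specific counting is not stated, so reads of overlapping antisense genes may not have been separated.

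Estimated counts per gene were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 6 combinations of genotype and treatment, which left 17732 genes, and libraries were scaled by TMM. A negative binomial quasi-likelihood model with 8 group means (glmQLFit, glmQLFTest) was fitted to all 14 libraries, with 6 residual degrees of freedom. The single libraries of the SE-line wild type were thereby assumed to vary like the other groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Every adjusted p of a single gene below comes from this test unless another tool is named. Comparisons were KCl against basal in wild type (3 cultures weighted equally), in SA and in SE, each mutant against the wild type of its line at basal and after KCl, and the difference in KCl response between each mutant and that wild type. Levels are CPM, counts scaled to the library total times its TMM factor, as mean ± SD, and log2 fold changes carry the standard error of the model.

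Lists of genes were fixed for 23 groups: immediate early genes, delayed response genes, MAPK feedback genes, BAF complex subunits, glutamate receptors, voltage-gated channels, markers of glutamatergic neurons, GABAergic neurons, neural progenitors, astrocytes, the oligodendrocyte lineage, microglia, endothelial and mural cells and meningeal fibroblasts, and genes of the cell cycle, cholesterol synthesis, glycolysis and hypoxia, heat shock and unfolded protein response, mitochondrially encoded respiration, ribosomal proteins, the interferon response, hedgehog targets and sex-linked genes. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the 23 lists of a comparison. Camera with a correlation estimated from the data and fry served as alternatives. Camera with the preset correlation called 40 list tests over the 9 comparisons, and 10 held with an estimated correlation. These were the immediate early, delayed response and MAPK feedback lists after KCl in wild type, SA and SE, and the GABAergic list after KCl in wild type. A further 2 lists, of choroid plexus markers and ATF4 targets, were written after the data were seen.

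Genes named below were taken from Smarca4, the up to 10 called genes that rose and 10 that fell most in a comparison with a mean of at least 1 CPM and no overlap between groups, and up to 4 members of each described list with the lowest p. Unnamed gene models were left out, and exceptions are marked as chosen after their values were seen. Not every gene that the rule takes is reported here. To compare KCl responses of mutant and wild type without choosing genes on the tested libraries, induced genes were picked in the other line. They were genes called with at least a 2-fold rise in a fit of the 6 SE-line libraries (249 genes, for SA) or of the 8 SA-line libraries (101 genes, for SE). The median difference in response was taken over them, and fry tested the set as a whole and not its median. The design, the tests, these lists and the naming rule were set before the data were examined.

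Library totals lay between 22625916 and 23096206 estimated counts, so depth differed little between libraries. On libraries simulated from a real mean per gene, 100 genes were changed 2-fold and 100 changed 4-fold per genotype among 17732. They were drawn from genes with a mean of at least 1 CPM. No difference between lines, and none shared by the libraries of a culture, was simulated, so recovery in the real data may be lower. The model recovered 51% and 98% for KCl in wild type, 49% and 89% in SA, and 58% and 91% in SE. For SA against wild type after KCl it recovered 63% and 90%, and for SE 38% and 88%. For the difference in KCl response it recovered 17% and 68% for SA and 9% and 69% for SE, with 7 to 17 false calls in these comparisons. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 8.67 to 63.6; Pearson r of log2 CPM over genes 0.9725 to 0.9908), so no library appeared to be deposited more than once. The labels do not say which litter a numbered replicate came from or whether it is 1 embryo, and p-values measure the spread between these cultures. Basal and KCl libraries of a group and number share a name stem in the deposited columns. The labels do not state that this stem marks a shared culture, nor that a number is shared between genotypes.

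Alternatives were RLE factors or no scaling, robust quasi-likelihood fitting, other low-count filters, an added fold-change threshold, DESeq2 1.42.0 on the same estimated counts, limma 3.58.1 (trend) on log2 of the deposited TPM plus 1 or plus 0.1, fits of 1 line alone, replicate blocks, pooling the wild types of both lines, and leaving out each library in turn. Leaving out wild-type culture 1 of the SA line was added after it was seen to stand apart. The per-transcript estimated counts were fitted in the same way for an additional account of 47808 transcripts. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88.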

Results

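RNA was profiled in 14 libraries of cultured mouse cortical neurons, 7 at basal and 7 after 1 h of 50 mM KCl. A basal and a KCl library of the same group and replicate number are called a culture below, although the labels do not state that they share one. BRG1, encoded by Smarca4, is the ATPase of the BAF chromatin remodelling complex. The mutants carry S1382A (SA), which cannot be phosphorylated at that residue, or S1382E (SE), whose glutamate is often used to mimic a phosphate. The series asks how this residue bears on transcription that follows neuronal activity. The SA line contributed 2 SA and 2 wild-type cultures, and the SE line contributed 2 SE cultures and 1 wild-type culture. Libraries held 22625916 to 23096206 estimated counts, with 24522 to 25622 gene symbols detected and 5.91% to 8.31% of counts from the mitochondrial genome.

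The lines differed more than any treatment or genotype. The first principal component of log2 CPM held 65.5% of the variance and separated the 8 libraries of the SA line from the 6 of the SE line. The second held 9.33%, and its lowest values belonged to both libraries of wild-type culture 1 of the SA line (-56.7 after KCl and -44.8 at basal). Mutants were therefore compared with the wild type of their own line. Sex-linked genes showed that SA culture 1 and wild-type culture 2 of the SA line were female, with Xist at 483 to 747 CPM. SA culture 2 and wild-type culture 1 were male, with Ddx3y at 30 to 56.9 CPM, so basal and KCl libraries of a number were of like sex in that line. The SE-line libraries held both Xist (147 to 301 CPM) and Ddx3y (11.0 to 21.4 CPM).

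**Figure D1:**
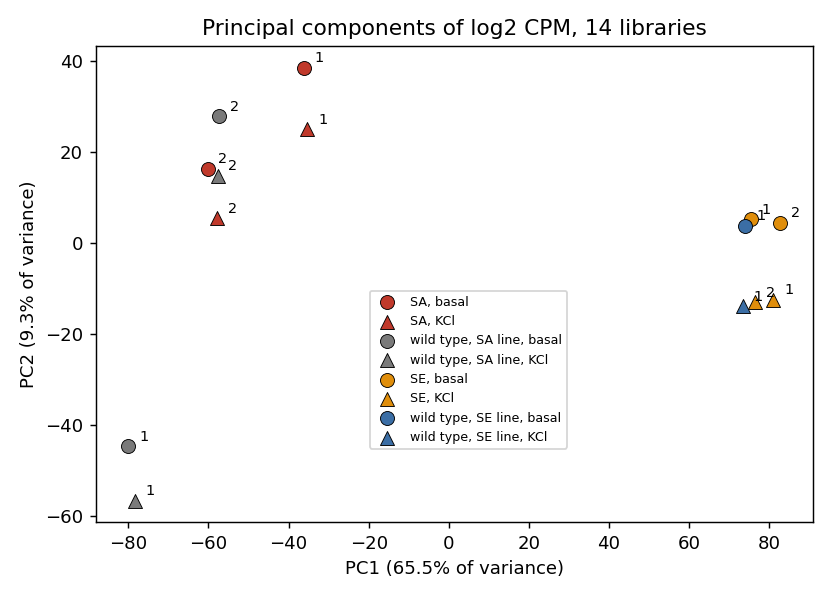
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library; colour marks line and genotype, and shape marks basal or KCl. The SA-line libraries lie left of zero and the SE-line libraries right of zero on component 1 (65.5% of variance), and wild-type culture 1 of the SA line lies lowest on component 2 (9.33%).

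Smarca4 (ENSMUSG00000032187.16, chromosome 9, 21616169 to 21704230, plus strand) was expressed at 427 ± 37 CPM (SD, n = 14), with a range of 373 to 504. Its largest absolute log2 difference over the 9 comparisons was 0.09, and its lowest adjusted p was 0.766. A changed codon need not alter the amount of transcript, so this level checks neither genotype label. In the 3 full-length protein models of GENCODE M21 (1614, 1617 and 1613 residues) residue 1382, encoded in exon 29, is not a serine, so the S1382 numbering belongs to another protein model and the edited codon was not placed on the genome.

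Depolarisation of wild-type neurons induced the immediate early genes strongly. Npas4, an activity-dependent transcription factor of neurons (chromosome 19, 4984355 to 4990316, minus strand), rose from 1.96 ± 0.488 to 516 ± 41.4 CPM in the wild type of the SA line (SD, n = 2), and over the 3 wild-type cultures its log2 fold change was 8.12 ± 0.185 (SE; 278-fold, adjusted p = 1.97e-08). Fosb, an AP-1 subunit (chromosome 7, 19302696 to 19310051, minus strand), rose by 8.83 ± 0.253 on the log2 scale, and its partner family member Fos (chromosome 12, 85473890 to 85477273, plus strand) rose 72.9-fold. Nr4a1, an orphan nuclear receptor (chromosome 15, 101254269 to 101274795, plus strand), rose 123-fold over the 3 wild-type cultures, and from 6.11 ± 0.594 to 602 ± 69.2 CPM in those of the SA line (n = 2). Egr1, a zinc finger transcription factor (chromosome 18, 34859823 to 34864984, plus strand), rose 43.8-fold, and Arc, a postsynaptic protein that regulates AMPA receptor trafficking (chromosome 15, 74669083 to 74672570, minus strand), rose 51.6-fold. Egr4, Egr2 and Junb rose by 7.41, 5.93 and 5.86 on the log2 scale. Of the 30 measured immediate early genes 28 rose and 2 did not pass (29 rose when adjusted over the list alone), with a median log2 change of 3.62 (camera with an estimated correlation, adjusted p = 2.6e-06).

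Genes of the delayed response, whose products act at synapses or are secreted, were already changing at 1 h in wild type. Of 24 measured, 11 rose and 13 did not pass (17 rose when adjusted over the list alone), with a median of 1.15 (adjusted p = 0.002 with an estimated correlation). Bdnf, a neurotrophin (chromosome 2, 109674700 to 109727007, plus strand), rose 9.55-fold (log2 3.26 ± 0.203, adjusted p = 2.2e-05). Scg2, a precursor of secreted neuropeptides, rose 4.03-fold over the 3 wild-type cultures, and from 25.9 ± 0.481 to 113 ± 15.9 CPM in those of the SA line (n = 2). Ptgs2, which encodes cyclooxygenase-2, rose 15.3-fold, and Pcsk1, a prohormone convertase, rose 12.3-fold. Among 15 genes of MAPK feedback 7 rose and 8 did not pass (10 rose when adjusted over the list alone; median 0.959, adjusted p = 0.00244 with an estimated correlation). They included the ERK phosphatase gene Dusp6 (4.21-fold), Dusp1 (6.84-fold), Spry2, an inhibitor of receptor tyrosine kinase signalling (2.42-fold), and Errfi1, an inhibitor of the EGF receptor (2.61-fold).

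Smaller rises appeared in 3 further lists in wild type. Of 15 heat shock and unfolded protein response genes 4 rose and 11 did not pass (5 rose when adjusted over the list alone): the HSP40 gene Dnajb1 by 1.10 on the log2 scale, Atf4, a transcription factor of the integrated stress response, by 0.95, and the endoplasmic reticulum genes Herpud1 and Dnajb9 by 0.57 and 0.55. Herpud1 lost its call in 15 of 23 alternatives (adjusted p up to 0.383), Atf4 in 7 and Dnajb9 in 3. The list passed camera (adjusted p = 4.36e-06) but not with an estimated correlation (adjusted p = 0.0956). Of 17 cholesterol genes 2 rose, among them Insig1, a sterol sensor, by 0.51, and 15 did not pass (6 rose when adjusted over the list alone; camera adjusted p = 4.18e-05, and adjusted p = 0.162 with an estimated correlation). Of 15 GABAergic neuron genes, Dlx5, a homeobox gene of interneurons, rose by 1.13 and 14 did not pass (2 rose when adjusted over the list alone). The GABAergic list passed camera (adjusted p = 1.42e-04) and held with an estimated correlation (adjusted p = 0.0486), but without wild-type culture 1 of the SA line that value was 0.11. No BAF subunit of 26 passed, nor did any when adjusted over the list alone (median log2 change -0.0285, camera adjusted p = 0.72; Smarcd2 had the lowest p, with -0.29 and an adjusted p of 0.468). In the remaining 16 lists camera gave adjusted p values from 0.221 to 0.994, and their 1 called member was Mycn, a MYC family gene of the hedgehog list, which was named after its values were seen and fell by 1.01.

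Fewer genes fell in wild type, and by less. Arrdc3, an arrestin-domain gene, fell by 1.65 on the log2 scale (adjusted p = 2.04e-04), from 132 ± 14.5 to 41.8 ± 0.347 CPM in the wild type of the SA line (n = 2). The zinc finger genes Zfp712 and Zfp786 fell by 1.87 and 1.55. In all, edgeR called 250 of 17732 genes in wild type (186 rose, 64 fell), of which 150 changed at least 2-fold, and 1253 genes had an unadjusted p under 0.05 where chance gives 887. With replicate number taken as a culture block 829 were called, although the labels do not state that pairing. Without wild-type KCl library 2 of the SA line 160 genes were called, and a fit of the 6 wild-type libraries alone called 33.

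**Figure D2:**
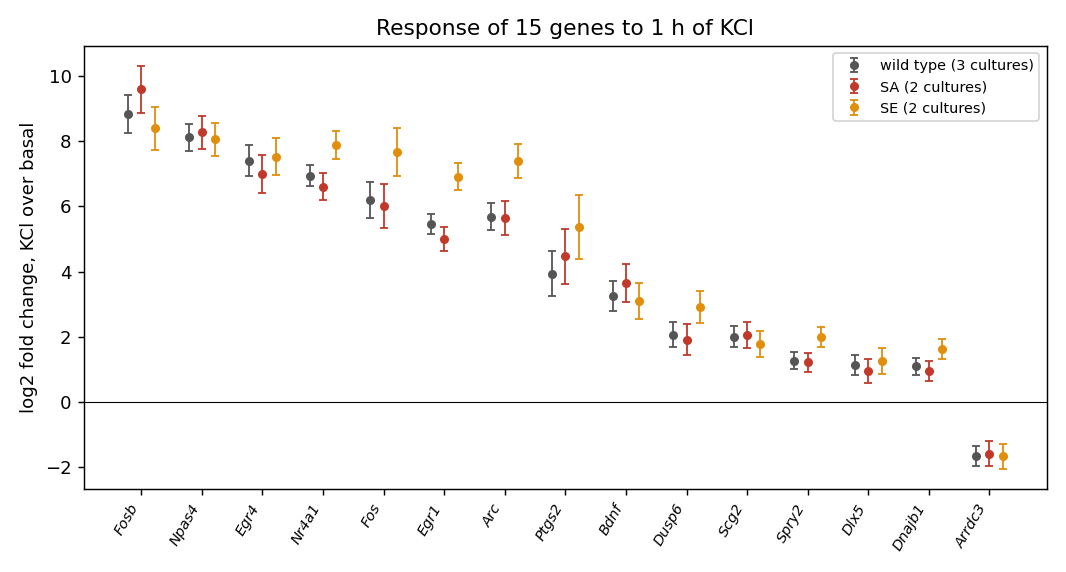
Log2 fold change of KCl over basal for 15 genes in wild type (3 cultures), SA (2) and SE (2), with 95% intervals of the edgeR model. The wild-type points average cultures of both lines, so they are not a within-line control for SA or SE. Npas4, Fosb and Nr4a1 lie above 6 in each genotype, and Arrdc3 lies below zero in each.

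In SA neurons KCl induced the same kinds of genes. Npas4 rose from 1.66 ± 0.233 to 513 ± 5.67 CPM (n = 2; log2 8.27 ± 0.231, 308-fold), Fosb by 9.59 and Fos by 6.03 on the log2 scale, and Nr4a1 by 6.60. Egr4, Nr4a2 and Klf4, all transcription factor genes, rose 128-fold, 38.4-fold and 34.9-fold. Egr1 rose 31.9-fold and Arc 49.9-fold. Of the 30 immediate early genes 25 rose and 5 did not pass (27 rose when adjusted over the list alone; median 3.08, adjusted p = 8.5e-06 with an estimated correlation). Among those that did not pass were Egr3 (log2 2.54, adjusted p = 0.0551) and Srf, which encodes serum response factor (0.53, adjusted p = 0.179). Of 24 delayed response genes 7 rose and 17 did not pass (16 rose when adjusted over the list alone; median 1.13, adjusted p = 0.00151 with an estimated correlation), with Bdnf at 12.6-fold, Scg2 at 4.17-fold, Ptgs2 at 22.1-fold and Pcsk1 at 17.2-fold. Of 15 MAPK feedback genes 5 rose and 10 did not pass (10 rose when adjusted over the list alone; median 0.65, adjusted p = 0.00815 with an estimated correlation), among them Dusp6 (3.79-fold), Spry2 (2.33-fold) and Errfi1 (2.54-fold).

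Dnajb1 (log2 0.96), Insig1 (0.47) and Dlx5 (0.95) also rose in SA, each with an adjusted p of at most 0.0363. Insig1 lost its call in 15 of 23 alternatives (adjusted p up to 0.307), Dlx5 in 6 and Dnajb1 in 4. They were among the called members of the heat shock (1 of 15, 4 when adjusted over the list alone), cholesterol (2 of 17, 5 when adjusted over the list alone) and GABAergic lists (1 of 15, 3 when adjusted over the list alone). These lists passed camera (adjusted p = 3.43e-04, 7.16e-04 and 0.00163) but not camera with an estimated correlation (adjusted p = 0.216, 0.268 and 0.096). By fry the GABAergic list passed (adjusted p = 0.0311), and the heat shock and cholesterol lists did not (adjusted p = 0.0956 and 0.063). No BAF subunit passed (median -0.0462, camera adjusted p = 0.505), and the other 16 lists gave camera adjusted p values from 0.0947 to 0.993. Txnip, which encodes a thioredoxin-binding protein, fell by 2.34 from 42.8 ± 4.75 to 8.41 ± 3.41 CPM (n = 2). It was likewise lower after KCl in the wild type of that line, at 45.6 ± 1.15 and 10.6 ± 2 CPM (n = 2). Arrdc3 fell by 1.59, the zinc finger genes Zfp39 and Zfp786 by 1.75 and 1.69, and Mycn by 1.18. Zfp39 also went from 12.7 ± 0.838 to 5.61 ± 0.953 CPM in the wild type of the SA line (n = 2). The edgeR test called 150 genes in SA (124 rose, 26 fell), 119 of them at least 2-fold, and 1033 had an unadjusted p under 0.05. It called 613 with replicate number taken as a culture block. With 2 libraries per arm each one mattered: 68 and 69 genes were called without SA basal library 1 or 2, and 75 and 80 without SA KCl library 1 or 2. DESeq2 called 253, and a fit of the SA line alone called 68.

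In SE neurons KCl induced these groups as well. Npas4 rose from 8.74 ± 0.646 CPM (n = 2) by 8.05 ± 0.221 on the log2 scale (265-fold), Fosb 337-fold, Nr4a1 235-fold and Fos 202-fold. Arc rose 166-fold, Junb 115-fold and Egr4 184-fold, Egr1 rose by 6.91 on the log2 scale, and Gadd45b, a stress-responsive regulator of DNA demethylation and MAPK signalling, rose by 5.63. The wild-type folds above average cultures of both lines and are not a within-line control for these. In the single wild-type culture of the SE line Arc rose from 6.62 to 944 CPM, against 6.5 ± 0.181 to 1080 ± 180 in SE (n = 2). Egr1 rose there from 23.5 to 2180 CPM and Fos from 8.59 to 1190. Of the 30 immediate early genes 29 rose and 1 did not pass (29 rose when adjusted over the list alone; median 4.68, adjusted p = 1.23e-05 with an estimated correlation). Of 24 delayed response genes 10 rose and 14 did not pass (13 rose when adjusted over the list alone; median 0.998, adjusted p = 0.0033 with an estimated correlation). Ptgs2 rose 41.2-fold, Bdnf 8.55-fold, Scg2 3.42-fold and Rgs2, a regulator of G protein signalling, 5.76-fold. Of 15 MAPK feedback genes 8 rose and 7 did not pass (11 rose when adjusted over the list alone; median 1.5, adjusted p = 0.00222 with an estimated correlation), among them Dusp6 (7.58-fold), Dusp4 (4.95-fold), Spry2 (3.96-fold) and Errfi1 (3.45-fold).

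Dnajb1 rose by 1.63 in SE and Herpud1 by 0.67, Insig1 by 0.66 and Dlx5 by 1.26. Herpud1 lost its call in 11 of 22 alternatives (adjusted p up to 0.354). These were among the called members of the heat shock (2 of 15, 7 when adjusted over the list alone), cholesterol (2 of 17, 6 when adjusted over the list alone) and GABAergic lists (1 of 15, 4 when adjusted over the list alone). The 3 lists passed camera (adjusted p = 6.38e-05, 9.95e-05 and 4.58e-04) but not camera with an estimated correlation (adjusted p = 0.153, 0.187 and 0.0712). The 13 genes of the mitochondrial genome had a median of -0.233 with none called (camera adjusted p = 0.0171, and adjusted p = 0.987 with an estimated correlation). No BAF subunit passed (median 0.0059, mean -0.0194, camera adjusted p = 0.951), and the other 15 lists gave camera adjusted p values from 0.475 to 0.954. Zfp85, a zinc finger gene, fell by 2.63 from 3.94 ± 0.23 to 0.632 ± 0.222 CPM (n = 2), Kbtbd8, a ubiquitin ligase adaptor, by 2.35, Arrdc3 by 1.65 and Mycn by 0.90. In the single wild-type culture of that line Zfp85 went from 4.29 to 0.642 CPM and Kbtbd8 from 4.34 to 0.779. The edgeR test called 295 genes in SE (216 rose, 79 fell), 210 of them at least 2-fold, and 1490 had an unadjusted p under 0.05. It called 1024 with replicate number taken as a culture block, although basal and KCl deviations of a number correlated at only -0.0512 in SE. Without SE basal library 1 or 2 it called 118 and 114, without SE KCl library 1 or 2 it called 131 and 145, and in a fit of the SE line alone 717.

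The called genes overlapped widely between genotypes. Of the 186 genes that rose in wild type 116 also rose in SA and 159 in SE, where independent lists would share 1.3 and 2.27. Of the 64 that fell, 21 fell in SA and 45 in SE (0.0938 and 0.285 if independent). SA and SE shared 109 rising and 16 falling genes, and 107 rose and 16 fell in all 3. No library is shared between these comparisons, although 1 estimate of dispersion is. A gene called in 1 genotype and not in another is not thereby shown to differ between them, which the tests of the response difference address.

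At basal, no gene was called between SA and its wild type. The largest group differences were lower meningeal fibroblast, cell cycle and interferon genes in SA. Postn, an extracellular matrix gene, was at 8.67 ± 0.083 CPM in SA and 20.8 ± 7.68 in wild type (n = 2 each; log2 -1.27 ± 0.307), Lum differed by -1.96 and Col1a1 by -0.92 (22.5 ± 1.88 against 42.5 ± 2.42 CPM). The 12 meningeal fibroblast genes were all lower (median -0.995, camera adjusted p = 6.42e-15; adjusted p = 0.241 with an estimated correlation), none passed over all genes, and 10 passed when adjusted over the list alone. The 18 cell cycle genes were all lower (median -0.478, camera adjusted p = 3.01e-06; adjusted p = 0.7 with an estimated correlation), with the mitotic genes Top2a at -0.78 and Mki67 at -0.69. Of 16 interferon response genes 15 were lower (median -0.962, camera adjusted p = 4.05e-06; adjusted p = 0.7 with an estimated correlation), with Ifit2 at 13.9 ± 1.36 and 22.6 ± 4.85 CPM. Each of these genes had an adjusted p of 0.621. Wild-type culture 1 stood apart here: without it the medians were -0.695 for meningeal (camera adjusted p = 5.31e-11; adjusted p = 0.332 with an estimated correlation), -0.0617 for cell cycle (adjusted p = 0.189) and -0.0896 for interferon genes (adjusted p = 0.357).

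Voltage-gated channel, cholesterol and mitochondrially encoded genes leaned higher in SA at basal (medians 0.269, 0.181 and 0.191; camera adjusted p = 0.0106, 0.00167 and 0.0127; adjusted p = 0.7 with an estimated correlation for each). Without wild-type culture 1 of the SA line the channel median was -0.11 (camera adjusted p = 0.122). Immediate early, delayed response, MAPK feedback and BAF genes had medians of -0.204, 0.175, -0.15 and 0.0279 (the BAF mean was -0.00734), with camera adjusted p values of 0.116, 0.328, 0.255 and 0.857 and no member called, over all genes or when adjusted over the list alone. By edgeR 0 genes passed, 1279 had an unadjusted p under 0.05 where chance gives 887, and the lowest adjusted p was 0.621. DESeq2 and limma on log2 TPM called 0 as well, and 1 gene was called without SA basal library 1. With the sex of each SA-line culture added to the model, a fit chosen after the data were seen, 16 were called, 15 of them lower in SA. The 95% interval of the difference lay inside 2-fold for 64.7% of genes and for 26 of 26 BAF subunits.

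**Figure D3:**
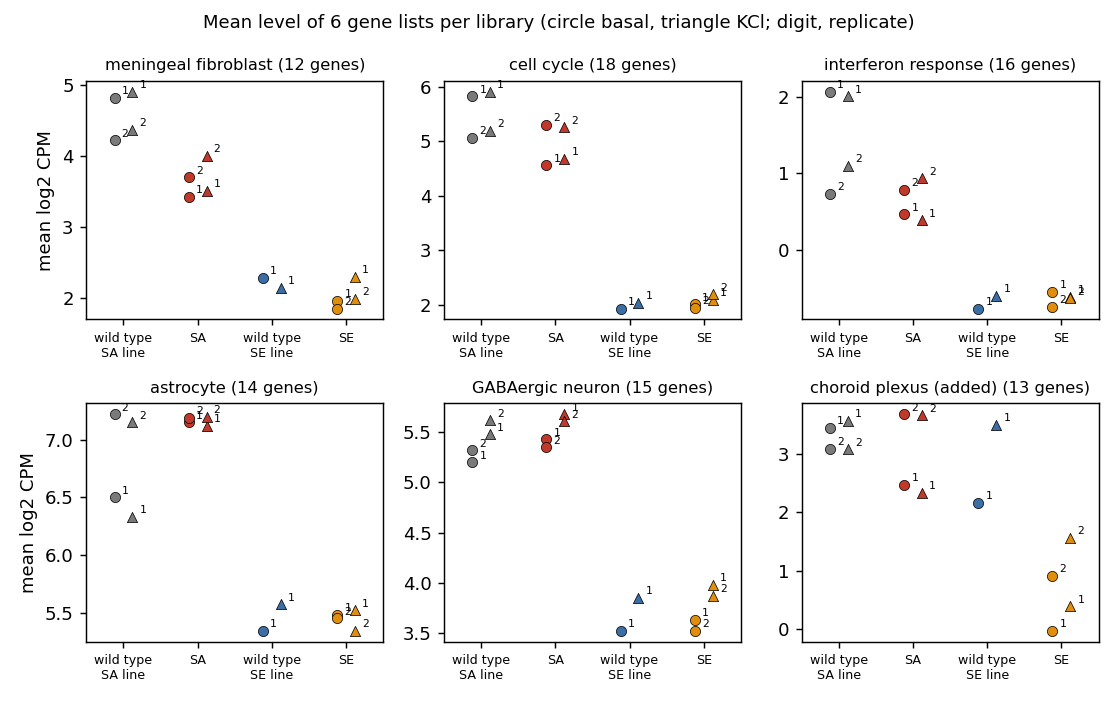
Mean log2 CPM of 6 gene lists in each library, by line and genotype; circles are basal and triangles KCl, and digits are replicate numbers. Meningeal fibroblast genes lie at 3.42 to 4 in the 4 SA libraries and at 4.22 to 4.90 in the 4 wild-type libraries of that line, with wild-type culture 1 highest.

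After KCl the same groups were lower in SA than in its wild type. Meningeal fibroblast genes had a median of -0.799, with 12 of 12 lower (camera adjusted p = 5.43e-09; adjusted p = 0.324 with an estimated correlation), and 8 passed when adjusted over the list alone. Postn was at 10.6 ± 1.5 CPM in SA and 21.2 ± 5.83 in wild type (n = 2 each), and the collagen gene Col3a1 differed by -0.95 on the log2 scale (adjusted p = 0.34 for both). Cell cycle genes had a median of -0.559 and interferon genes of -1.02 (camera adjusted p = 3.21e-06 and 1.06e-05; adjusted p = 0.701 with an estimated correlation for both). Their examples were Top2a at -1.02, Mki67 at -0.91 and Ifit2 at -0.78, with adjusted p values of 0.335, 0.345 and 0.335. Endothelial and mural genes were lower (median -0.448, camera adjusted p = 0.0238; adjusted p = 0.324 with an estimated correlation) and mitochondrially encoded genes higher (0.235, camera adjusted p = 0.00931; adjusted p = 0.711 with an estimated correlation). Without wild-type culture 1 the medians were -0.558 for meningeal, -0.12 for cell cycle, -0.232 for interferon, -0.702 for endothelial and mural and 0.0167 for mitochondrially encoded genes.

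The activity-regulated lists were close between SA and wild type after KCl. Npas4 was at 513 ± 5.67 CPM in SA and 516 ± 41.4 in wild type, Fos at 438 ± 24.2 and 457 ± 61.6, and Arc at 88.4 ± 17.9 and 81.3 ± 4.26 (n = 2 each). Medians were 0.0402 for immediate early, 0.138 for delayed response, 0.0308 for MAPK feedback (mean -0.0387) and -0.00793 for BAF genes (camera adjusted p = 0.527, 0.108, 0.745 and 0.834). Gadd45b had the lowest p of the immediate early genes in SA (0.53 higher, adjusted p = 0.396). Pbrm1, which encodes the PBAF subunit polybromo-1, was at 62.7 ± 4.8 CPM in SA and 96.7 ± 6.21 in wild type (log2 -0.62, adjusted p = 0.299), and passed when adjusted over the list alone. By edgeR 0 genes passed, with 2040 at an unadjusted p under 0.05 and a lowest adjusted p of 0.299; limma on log2 TPM called 0, whereas DESeq2 called 126, of which 122 were lower in SA. With the sex of each SA-line culture added, again chosen after the data were seen, edgeR called 853, of which 642 were lower in SA. Without sex in the model the number was 1 without SA KCl library 2 and 1 without wild-type KCl library 2. The 95% interval lay inside 2-fold for 62.9% of genes and for 25 of 30 immediate early genes.

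The difference in KCl response between SA and wild type asks whether the alanine alters induction. Over the 249 genes induced in the other line, the median response was 0.101 higher in SA on the log2 scale (152 higher, 96 lower), and over the 30 immediate early genes it was 0.174 higher (20 higher, 10 lower). Neither set passed fry at 0.05. With libraries of a number taken as 1 culture, the mean response of immediate early genes was 3.67 ± 0.17 in SA (12.7-fold) and 3.5 ± 0.2 in wild type (11.3-fold; n = 2 cultures each; exact two-sided permutation p = 0.667, and the same for induced genes, where the smallest possible is 0.333). Camera passed for the immediate early list (adjusted p = 9.06e-04; adjusted p = 0.966 with an estimated correlation). Its members with the lowest p were Arc (0.68 ± 0.288 higher), Klf4 (1.44 higher) and Gadd45b (0.69 higher), and Nr4a2 was at -0.35, each with an adjusted p of 1. Delayed response, MAPK feedback and BAF genes had medians of 0.057, -0.0527 (mean 0.113) and 0.0055 (mean -0.0136), with camera adjusted p values of 0.557, 0.557 and 0.953. Single cultures moved these values: without wild-type culture 1 of the SA line the medians were -0.00356 for induced and 0.0127 for immediate early genes, and without its basal library alone they were -0.0094 and -0.0247. Without SA basal library 1 they were 0.0244 and 0.0617, without SA basal library 2 they were 0.225 and 0.268, and without wild-type basal library 2 they were 0.155 and 0.385.

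No gene passed the test of the response difference for SA. By edgeR 0 genes were called, 122 had an unadjusted p under 0.05, fewer than the 887 that chance gives, and DESeq2, limma on log2 TPM and the fit with sex called 0. Deviations of libraries of a number correlated between basal and KCl (r = 0.422 in SA and 0.67 in wild type). The unpaired fit counts such shared deviations as spread, so its p-values can be too high and its intervals too wide. A fit with replicate number as a culture block called 0 as well. The 95% interval lay inside 2-fold for 58.2% of genes and for 15 of 30 immediate early genes, so larger differences in the other genes are not excluded.

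**Figure D4:**
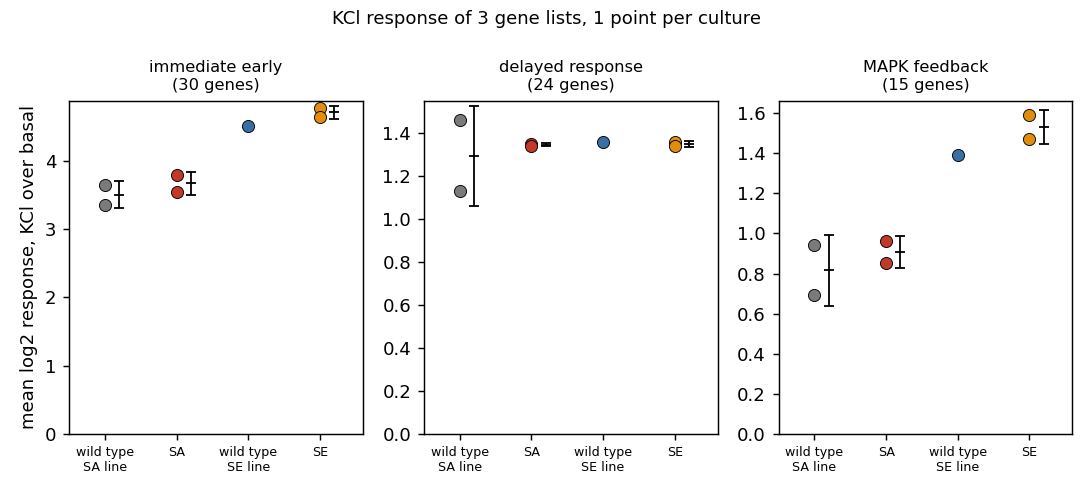
Mean log2 response to KCl of the immediate early, delayed response and MAPK feedback lists, 1 point per culture; bars give the mean and SD where there are 2 cultures. Immediate early responses lie at 3.36 to 3.79 in the 4 SA-line cultures and at 4.51 to 4.78 in the 3 SE-line cultures, whereas delayed responses lie at 1.13 to 1.46.

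SE neurons and the 1 wild-type culture of their line were compared with the spread of the other groups, since that wild type has no replicate. SE replicates differed less (chi-square per degree of freedom 8.67 at basal and 9.255 after KCl) than those of the SA-line groups (17.6 to 63.6). The shared spread can thus be too wide for this line, and 0 calls do not show that SE equals wild type. At basal, meningeal fibroblast genes were lower in SE (median -0.391, camera adjusted p = 5.91e-04; adjusted p = 0.943 with an estimated correlation), with Col1a1 at -0.87, and mitochondrially encoded genes were lower (-0.197, camera adjusted p = 0.00367; adjusted p = 0.943 with an estimated correlation). Markers of choroid plexus, listed after the data were seen, moved with them (13 genes, median -1.48). Npas4 was at 8.74 ± 0.646 CPM in SE (n = 2) and 6.21 in wild type (log2 0.49, adjusted p = 1). Immediate early, delayed response, MAPK feedback and BAF genes had medians of -0.0465, 0.116, -0.0463 and 0.0185 (camera adjusted p = 0.646, 0.449, 0.646 and 0.92). By edgeR 0 genes passed, and 187 had an unadjusted p under 0.05, fewer than the 887 that chance gives. DESeq2 called 0, while limma called 1 on log2(TPM + 1) and 2 on log2(TPM + 0.1). The 95% interval lay inside 2-fold for 62.7% of genes.

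After KCl, immediate early genes leaned higher in SE than in wild type (median 0.132, 28 of 30 higher, camera adjusted p = 0.00206; adjusted p = 0.907 with an estimated correlation). Egr4 was 0.34 and Nr4a1 0.22 higher on the log2 scale (adjusted p = 1 for both). Mitochondrially encoded and ribosomal protein genes were lower (medians -0.17 and -0.113, camera adjusted p = 0.00629 and 0.0103; adjusted p = 0.907 with an estimated correlation for both). Delayed response, MAPK feedback and BAF genes had medians of 0.129, 0.122 and 0.0276 (camera adjusted p = 0.212, 0.39 and 0.77). By edgeR 0 genes passed and 240 had an unadjusted p under 0.05, again fewer than the 887 of chance. DESeq2 called 1 and limma 2 on log2(TPM + 1) and 0 on log2(TPM + 0.1). Choroid plexus markers had a median of -1.7. A fit of the SE line alone called 12, all lower in SE, and 1 gene was called without SA KCl library 1 and 1 without SA KCl library 2.

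The response of immediate early genes was 4.71 ± 0.099 in the 2 SE cultures (26.2-fold) and 4.51 in the wild-type culture (22.8-fold). The gene-wise median difference was 0.222 (26 of 30 higher in SE), and over the 101 genes induced in the other line it was 0.162 (76 higher, 25 lower). Neither set passed fry at 0.05. Without SE KCl library 1 or 2 the first median was 0.138 and 0.325. Fosl2, an AP-1 family gene, Egr1 and Fos had response differences of 0.42, 0.37 and 0.55 (adjusted p = 1 each). Camera passed for immediate early (adjusted p = 0.00546), astrocyte (median -0.269, adjusted p = 0.0335), meningeal (0.325, adjusted p = 0.0271) and ribosomal protein genes (-0.156, adjusted p = 0.0107), and adjusted p = 0.997 with an estimated correlation for each. Choroid plexus markers moved in the same comparison, with mean responses of 1.33 in the wild-type culture and 0.422 and 0.652 in SE. Delayed response, MAPK feedback and BAF genes had medians of 0.0288 (mean -0.0105), 0.155 and -5.37e-05 (mean 0.0103; camera adjusted p = 0.993, 0.211 and 0.993). By edgeR 0 genes passed and 159 had an unadjusted p under 0.05, where chance gives 887. DESeq2 called 1, limma 2 on log2(TPM + 1) and 3 on log2(TPM + 0.1), and edgeR with replicate number as a culture block 2. The number was 1 without SA KCl library 1 and 1 without SA KCl library 2. The 95% interval lay inside 2-fold for 14 of 30 immediate early genes.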

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

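The comparison of the SE line with the SA line, the marker lists for choroid plexus, and the tests of the SE genotype, of basal level, of wild-type culture 1, of neuron share and of choroid plexus genes were chosen only after the results were seen. The tests of scaling and of other groupings of libraries were planned, but for the lines they were applied to a comparison chosen after the results were seen. The lines also differ in culture and in whatever else accompanied their preparation, none of which the labels separate.

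The KCl response differed between the lines, by a test of the difference itself. It differed in 27 genes, of which 24 responded more in the SE line and 3 less (546 at an unadjusted p under 0.05), and in 2 genes, Arl4d and Nr4a2, when wild-type cultures alone were compared. The immediate early list had a median line difference of 1.19 on the log2 scale, with 8 of 30 genes called higher and 1 lower (adjusted p = 0.00636 with an estimated correlation). MAPK feedback genes had a median of 0.519, with Dusp4 called (adjusted p = 0.017 with an estimated correlation), and delayed response genes one of -0.00525 with none called. Cyr61, a matricellular gene, responded more by 4.34, the stress-induced transcription factor gene Atf3 by 3.08, Arc by 2.01, Jun by 1.98 and Egr1 by 1.83. Over basal and KCl libraries together the lines also differed in cell type markers, with GABAergic genes at a mean log2 CPM of 3.73 ± 0.2 in the SE line (SD, n = 6) and 5.46 ± 0.17 in the SA line (n = 8), astrocyte genes at 5.45 ± 0.095 and 6.98 ± 0.35, cell cycle genes at 2.04 ± 0.099 and 5.23 ± 0.48, and glutamatergic genes at 6.43 ± 0.035 and 5.58 ± 0.18. Of these lists only the GABAergic one passed at basal when tested with an estimated correlation (adjusted p = 0.00222), and the others did not (adjusted p = 0.155, 0.155 and 0.156 with an estimated correlation). Nr4a2 responded less (-2.99), from a basal level of 104 ± 4.49 CPM in the SE line (SD, n = 3) against 4.24 ± 0.772 in the SA line (n = 4).

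Technical and biological explanations were weighed for this larger immediate early response. Scaling does not account for it, because the median line difference stayed at 1.18 with library totals alone. Nor does a higher basal level in the SA line account for the list as a whole. Its mean basal level was 0.372 ± 0.087 (standard error) higher in the SE line. For single genes it is not excluded: at basal 10 of 30 members were called higher and 7 lower in the SE line. Cyr61 and Jun stood at log2 -2.28 and -1.36 there against the SA line, and Dusp4 of the MAPK feedback list at -1.65. With a level fitted per culture, 184 genes differed in response, and 1 of 35 splits of the 7 cultures, the real one, gave as many (highest other 135). The split by line was chosen after the lines were seen to differ, so this count does not measure chance. The wild-type culture of the SE line responded above the highest SA-line culture by 0.72, against an SD between cultures of 0.161. With wild-type cultures alone the median line difference of the immediate early list was 1.27. The larger response was thus seen without the SE substitution, but in 1 culture only. That culture cannot show how much the line and the SE genotype each contribute. The different mix of cells in the lines stays open, untested.

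Lower cell cycle, interferon and meningeal fibroblast genes in SA were weighed against wild-type culture 1 of the SA line, whose libraries stood apart. After KCl the medians without it were -0.12 for cell cycle and -0.232 for interferon genes, which does not settle what that culture gave there. At basal without it the median was -0.0617 for cell cycle and -0.0896 for interferon genes, which is what that culture alone would give. For meningeal fibroblast genes it was -0.695, so that culture alone does not account for them, although the list did not pass with an estimated correlation (adjusted p = 0.332). A lower share of neurons in that culture was taken to raise markers of all other cell types. Astrocyte genes were lower there (-0.621 between the nearest libraries). This cannot decide, because other cell types can also differ in share among themselves. Voltage-gated channel genes were lowest there too (4.96 and 5.05 log2 CPM against 5.52 to 5.9), as were glutamatergic genes (5.35 and 5.39). GABAergic genes (5.2 and 5.48) overlapped the other cultures of that line. A lower share of neurons therefore stays open. An effect of the SA genotype on meningeal genes and the number of meningeal cells carried into each culture remain open and were not tested.

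Choroid plexus genes leaned higher in the single wild-type culture of the SE line than in SE (medians of SE minus wild type -1.7 after KCl and -1.48 at basal), although none of the 13 passed after KCl (adjusted p = 1 each) and the medians include 4 genes among the 50 of lowest p, with Ttr, a transthyretin gene, at 506 CPM in the wild-type KCl library, 167 in its basal library and 0.722 to 60.3 in the SE libraries. Choroid plexus cells in that culture are a possible explanation. All 9 markers outside the 50 genes of lowest p were highest in that KCl library among the 6 of the SE line, as were all 13 tested, whereas Ttr reached 740.0 CPM in the SA line. The list was written after these libraries were seen, so the markers restate the pattern and cannot decide for such cells. A KCl response of these genes cannot be told apart from such cells. Their highest mean log2 response in the wild-type cultures of the SA line was 0.121, but it was 0.422, 0.652 and 1.33 in SE cultures 1 and 2 and the wild type of the SE line. Such a response would leave the basal difference unexplained. None of the 13 is in a list fixed beforehand.

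Transcript estimates, which the comparisons of genes do not use, held signals above their basal controls, among them transcripts of Homer1 and Bdnf. The Homer1 transcript ENSMUST00000102752.9 (5 exons, chromosome 13, 93304495 to 93360462) rose by 3.48 on the log2 scale in wild type (adjusted p = 0.00412), by 3.27 in SA and by 3.26 in SE, whereas the 9-exon ENSMUST00000079086.7 stood at -0.07 (adjusted p = 1). The Homer1 transcript ENSMUST00000109492.8 (6 exons) rose by 7.15 in wild type (adjusted p = 0.0182) and by 6.18 in SE (adjusted p = 0.0446), and stood at 6.71 in SA (adjusted p = 0.0794). Its basal level was near zero, at 0.0746 ± 0.0542 CPM in the SA line (SD, n = 4) and 0.24 ± 0.246 in the SE line (n = 3). After KCl it was at 10.9 ± 2.84 and 17.2 ± 2.13 CPM. The size of its log2 changes is therefore uncertain. The Bdnf transcript ENSMUST00000111050.9 (chromosome 2, 109692436 to 109727007) rose by 5.46 (adjusted p = 0.00165) in wild type. Over the 4 SA-line cultures, SA and wild type together, it went from 0.432 ± 0.173 to 21.8 ± 6.56 CPM (SD).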

How the results depend on the processing

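Leaving out wild-type culture 1 of the SA line and the crossed block were chosen only after the results were seen. For genes that passed and are named in the report, 76 results were refitted, each in several alternatives. Of the 1723 values this gave, all kept their direction and 1625 their call. Each alternative fit is counted once per result, so these values are not independent. Many of these genes were named for large changes without overlap, which makes a kept direction likely. Named genes that had not passed stayed so in 636 of 655 such values, passed in 14 and turned in 5. Smarca4 passed in 0 of 28 alternatives (largest absolute log2 difference 0.229). The count of genes with a different KCl response in SA was 0 in all 27 alternatives. What depth and the number of libraries each limit was not compared. Where an alternative leaves 1 library in a group, it is assumed to vary like the others. The cause was not tested for any change below, except that fewer libraries leave fewer degrees of freedom.

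Of 40 list calls 10 were left with an estimated correlation and 16 with fry. Genes changed by KCl were 613 in SA, 1024 in SE and 829 in wild type with replicate number as a culture block, and 68, 717 and 33 in the line alone (both lines' wild types for the last). DESeq2 called 253 in SA, and 150 in wild type changed at least 2-fold. Without 1 library the counts were 68 to 167 in SA, 114 to 299 in SE and 160 to 236 in wild type.

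For SA against wild type after KCl DESeq2 called 126 and the range without 1 library was 0 to 1, as at basal. Replicates of SA and wild type correlated across numbers, and a crossed block, which is the fit with sex of the report, called 853 after KCl and 16 at basal; shared numbers are not shown to be pairs, and a litter block called 0 in both and 144 for KCl in SA. For SE against wild type after KCl the count was 1 with DESeq2, 2 on log2(TPM + 1), 3 with no filter, 12 in its line alone and 0 to 1 without 1 library. At basal it was 2 on log2(TPM + 0.1), 1 on log2(TPM + 1), 3 in its line alone and 0 to 0 without 1 library. For the response difference of SE it was 2 in the culture block, 1 with DESeq2, 3 on log2(TPM + 0.1), 2 on log2(TPM + 1), 1 in its line alone and 0 to 1 without 1 library. Other counts of these comparisons stayed at 0.

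With the wild types of both lines pooled the SA median response difference turned to -0.206 for immediate early and -0.123 for induced genes, and the SE medians were 0.392 for induced genes, which passed fry, and 0.831 for immediate early genes, which did not; this pooling mixes lines that respond differently. Pooling also turned Arc (-0.91), Gadd45b (-0.14) and Nr4a2 (2.28) in the SA response and Gadd45b (-0.41) in SA after KCl. Without wild-type culture 1 induced genes turned to -0.00356 and Klf4 to -0.017. Without 1 library the immediate early medians were -0.0247 to 0.385 for SA and 0.138 to 0.325 for SE, and the induced medians -0.0094 to 0.225 and 0.127 to 0.205.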

Other observations

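The comparisons of lines at basal and the ATF4 target list in this part were chosen only after the data were seen. At basal 8483 genes differed between the lines (3866 higher and 4617 lower in the SE line), and 5067 when only wild-type cultures were compared. Markers of dividing cells and of several cell types other than glutamatergic neurons were lower in the SE line. Counts here are of genes called, and medians are over all tested members of a list. All 18 cell cycle genes were called lower (median log2 difference -3.69), as were 11 of 12 oligodendrocyte lineage (-3.06), 11 of 13 neural progenitor (-2.51), 11 of 14 astrocyte (-1.82), 12 of 12 meningeal fibroblast (-2.18), 10 of 13 microglia (-1.53) and 12 of 15 GABAergic genes (-1.92). With an estimated correlation the oligodendrocyte and GABAergic lists passed (adjusted p = 0.00161 and 0.00222), and the others had adjusted p values of 0.155, 0.103, 0.155, 0.155 and 0.222 in the order given. Interferon response (11 of 16 called lower, median -2.68), hedgehog (7 of 9, -2) and choroid plexus genes (12 of 13, -2.09) were lower too, with adjusted p = 0.514, 0.155 and 0.514 with an estimated correlation.

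Glutamatergic neuron genes leaned higher in the SE line (median 0.75, 7 of 15 called higher and 3 called lower, adjusted p = 0.156 with an estimated correlation). So did targets of ATF4, a transcription factor of amino acid stress (1.33, 10 of 16 called higher, adjusted p = 0.488 with an estimated correlation). Over libraries the ATF4 targets had a mean log2 CPM of 6.18 ± 0.088 in the SE line (SD, n = 6) and 4.66 ± 0.59 in the SA line (n = 8), with wild-type culture 1 highest of the latter at 5.45 and 5.75.

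Planned counts over other splits of the libraries were made for comparisons with at least 3 libraries a side. For the line difference at basal 1 of 35 splits of the 7 basal libraries, the real one, called as many genes (8302 in that fit, highest other 1684). The lines were compared after they were seen to differ, so this count does not measure chance. For KCl in wild type 1 of 10 splits of the 6 libraries called as many (33, highest other 0), and 10 splits are too few to go lower.

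Over 47808 transcripts, KCl changed 218 in wild type (189 rose, 29 fell), 94 in SA and 256 in SE. None of the genes whose transcripts passed between a mutant and its wild type was called as a gene. The error of kallisto's split of reads among transcripts was not measured. For SE the wild type had 1 library per treatment, so its transcript calls rest on the spread of other groups and do not show an effect of SE. Between SA and wild type 1 transcript passed at basal, 0 after KCl and 0 for the difference in response. Between SE and wild type 7 passed at basal, 0 after KCl and 11 for the difference in response.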
